A study of Homo sapiens with 6 samples.

How the data were processed

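RNA was profiled in human neural stem cells derived from the established embryonic stem cell line H9. Per the labels' protocols, cells were electroporated with a plasmid for a constitutively active form of the transcription factor MEF2 (MEF2CA) or with the matching vector that carries only the fluorescent protein tdTomato. Total RNA was extracted, amplified to cRNA, labelled with Cy3 and hybridised to Illumina bead arrays. There were 6 arrays in 2 groups of 3, and each array was assigned to its group and replicate number by its title.

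The deposited table of probe intensity values is on a linear scale and was not normalized between arrays, as its differing array quartiles show. Its lowest value on any array lies above 0, so background had not been subtracted. Beside each value, the deposited table gives a detection p-value per probe and array, named so per the file headers, whose values move in steps of 1 over 770. GenomeStudio is the software named per the submitters' processing notes, and its version is not given in the sources used here. A second deposited table holds intensity values of the same arrays on a linear scale, with a common distribution across arrays and a median of 197.6 to 197.7 per array. Each of its columns ranked the probes as the matching column of the first table did (Spearman's rho of 1 across probes after rounding), so it was read as a quantile-normalized version, without centring, and used only as an alternative. How the authors summarised beads to probes is not given in the sources used here.

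Intensities were processed with limma 3.58.1 in R 4.3.3. The neqc procedure estimated the background of each array from the detection p-values, applied normexp correction with an offset of 16, quantile normalization and a log2 transformation. Of 47225 probes, the 22086 with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept. A linear model with group as the only term was fitted to each kept probe (lmFit and eBayes, two-sided moderated test with 6.937 degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over all kept probes with a threshold of 0.05. Unless an alternative fit is named beside it, an adjusted p-value of a probe given in the results comes from this limma fit. Values are given as mean log2 intensity ± SD over 3 arrays, and differences as log2 fold changes of MEF2CA over vector control with their standard error (SE).

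A probe that was detected on 0 of 3 arrays of a group has only an upper bound there. For such a probe the fold is given as "at least N-fold": the mean of the brighter group against a mean over the arrays of the dimmer group, where each array contributes its lowest normalized signal among detected probes or the probe's own value, whichever is higher. The means of lists are given with such members at their bounds, and the medians are of fitted values, with the bounded median beside it where the 2 differ. The 6 arrays limit the precision of all values. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Slides are not identified in the files, and no batch could be tested.

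Probes were named through the platform annotation: 30111 probes have 1 gene symbol, 8 have several and 17106 are unnamed here. Symbols were compared with the RefSeq gene table of assembly GRCh38.p14, and 0 needed updating. No coordinates are given, since the build behind the array design is not named in the sources used here. Kept probes name 12680 genes, of which 3365 have more than 1 kept probe.

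Before the data were examined, 32 gene lists were fixed, covering MEF2 genes and described MEF2 targets, muscle, neural and other cell types, stress, metabolism and signalling. Of 758 list entries, 2 could not be matched to 1 gene. In each list, a gene was represented by its kept probe with the highest mean intensity. Lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists. Camera with an estimated correlation and fry were run beside it. Members past the test were counted with adjustment over all kept probes and, separately, adjusted over the list alone.

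The rule for naming genes was also fixed beforehand. It takes the MEF2 family, then the 16 genes with the largest increase and the 12 with the largest decrease among probes past the test with no overlap between groups and detection on all 3 arrays of the higher group, passing over provisional symbols. From each list it takes up to 4 members with the largest change among those past the test, or the 2 brightest members where none passed. Genes named because they were not detected, and those named in the closing section by gene family, as leukocyte markers or by disagreeing probes, fall outside this rule and were chosen after their values were seen.

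The fit was tested on simulated data made from these arrays, with 22086 probes and known changes between MEF2CA and control. It recovered 30% of 50 probes simulated with a 1.5-fold change and 64% of 50 with a 2-fold change. Of 50 probes each with a 4-fold and an 8-fold change, it recovered 92% and 94%. Noise was normal and independent between probes, and no other probes were changed. The changed share was thus far below the 28.5% of probes past the test in the real data. The adjusted threshold is stricter when fewer probes change, so these rates may understate recovery in the real fit. Alternatives covered the background correction, the normalization, the deposited normalized table, the filter on dim probes, the variance model, array weights, averaging of a gene's probes, the replicate number as a block and leaving out each array in turn. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.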

Results

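The series asks which genes depend on MEF2 in human neural stem cells. Its arrays cover added active MEF2 and no loss of MEF2, so a need for the cells' own MEF2 was not tested. MEF2 proteins are MADS-box transcription factors that act in muscle, neurons and other tissues. Cells derived from H9 embryonic stem cells received constitutively active MEF2 (MEF2CA) or the tdTomato vector, and RNA was measured on 3 arrays per group. Mean raw intensity was 1361, 1436 and 1287 on the control arrays and 1205, 1193 and 1233 on the MEF2CA arrays. Between 20962 and 22044 probes were detected on the control arrays and between 21823 and 22593 on the MEF2CA arrays. Raw log2 intensities correlated across probes at 0.994 within each group and at 0.977 to 0.978 between groups.

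Of 22086 probes tested, 3044 were higher and 3241 were lower with MEF2CA, together 28.5% of the probes. They name 2136 genes with a higher probe and 2358 with a lower probe, and 13 genes appear on both sides through different probes. Large changes were mostly increases: 1213 probes rose and 699 fell by at least 2-fold, 424 rose and 72 fell by at least 4-fold, and 78 rose and 1 fell by at least 16-fold. With probes undetected in 1 group set to their bounds, these numbers were 1065 and 657, 362 and 64, and 56 and 1. The groups did not overlap for 44.8% of the probes, where chance gives 10%. The numbers of higher and lower probes depended on the scaling. With scaling by the array median, 2467 probes were higher and 4379 lower, so that 36.0% of the changed probes were higher, against 48.4% with quantile normalization. Cyclic loess moved the balance the other way, with 3434 higher, 2612 lower and 56.8% of the changed probes higher. Fold sizes depended on the background correction, and without it 907 probes passed the test with at least a 2-fold change, against 1912 with it.

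**Figure D1:**
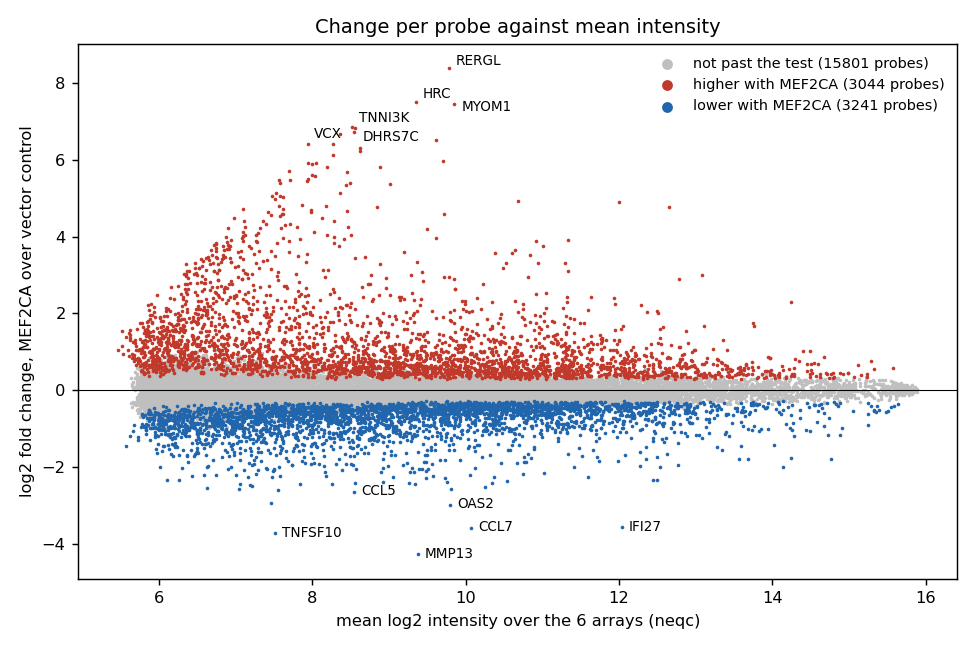
Log2 fold change of MEF2CA over vector control (vertical axis) against the mean log2 intensity over the 6 arrays (horizontal axis) for the 22086 probes tested. Red points are the 3044 probes higher with MEF2CA, blue points the 3241 lower probes and grey points those not past the test. Points of probes undetected in 1 group, such as RERGL at the top (at least 254-fold higher), are fitted values and not bounds. The lowest point is MMP13 (-4.29).

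Transcripts of 3 MEF2 genes rose moderately. MEF2A rose by a log2 fold change of 1.18 (SE 0.20, adjusted p = 0.0045), MEF2C by 0.81 (SE 0.13, adjusted p = 0.0040) and MEF2D by 0.64 (SE 0.12, adjusted p = 0.0075). MEF2C was at 7.40 ± 0.08 in the controls and 8.21 ± 0.22 with MEF2CA (SD, n = 3). Whether the probes can detect the transfected construct is not given in the sources used here, so these values do not check the transfection. MEF2B was not analysed here. The MEF2 family list passed the list test (adjusted p = 0.039, adjusted over the list alone 3 of 3 members higher), but not with an estimated correlation (adjusted p = 0.31). Without MEF2CA replicate 2 the list did not pass (adjusted p = 0.060), and over all alternatives its adjusted p ranged from 0.0090 to 0.060.

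The genes that rose most encode muscle proteins and a range of products of other tissues. RERGL, a RAS-like protein, rose at least 254-fold (adjusted p = 2.9e-07), from below detection in the controls to 13.98 ± 0.03 on the log2 scale. HRC, a calcium-binding protein of the sarcoplasmic reticulum, was also undetected in the controls and rose at least 139-fold. The M-band protein MYOM1 rose by 7.46 (SE 0.28) and was detected on 1 of 3 control arrays. TNNI3K, a cardiac kinase that binds troponin I, was at least 62.1-fold higher, and the muscle dehydrogenase DHRS7C at least 63.3-fold. TNNC1, cardiac and slow muscle troponin C, was at least 40.4-fold higher, and HSPB7, a small heat shock protein of heart muscle, at least 30.0-fold (both undetected in the controls). Among genes not specific to muscle, the metalloelastase MMP12 rose at least 45.2-fold, the cartilage collagen COL9A1 at least 36.1-fold, LGI1, a secreted protein of neurons, at least 53.8-fold and the immunoglobulin joining chain JCHAIN at least 32.2-fold. REEP1, a shaper of the endoplasmic reticulum, rose by 6.53 (SE 0.23, detected on 2 of 3 control arrays). All 16 genes of this group had an adjusted p of 5.7e-06 or less. Every MEF2CA array lay above every control array, as the rule for naming required.

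Some of these increases belong to single probes or to near-identical gene copies. VCX and VCX3B, which rose at least 60.3-fold and 55.4-fold, are copies of each other, so their probes may not separate them. AMY2A, an amylase of a family of close copies, rose by 5.97 on 1 probe and stood at 0.02 on another (adjusted p = 0.96, detected on 1 control and 2 MEF2CA arrays). RTN4, which shapes the endoplasmic reticulum, rose at least 52.4-fold on 1 probe, undetected in the controls, while its other probes rose by 0.46 and 0.44. The other probe of COL9A1, detected on 1 of 3 control arrays, rose by 1.73 and that of LGI1 at least 13.4-fold (both past the test).

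Genes described elsewhere as MEF2 targets moved as a group. Of 24 measured members, 17 rose, 2 fell and 5 did not pass, or 18 and 2 adjusted over the list alone, with a median log2 fold change of 2.01 (list adjusted p = 6.4e-11). HRC, MYOM1, TNNC1 and HSPB7 were among those that rose. The sarcomere list behaved alike in count, with 25 of 34 members higher and 2 lower, the same numbers adjusted over the list alone (median 1.74, list adjusted p = 5.9e-13). Its median was 1.29 when the 9 members not detected in the controls were set to their bounds, and 0.81 both without background correction and from the deposited normalized values. Under these 2 settings the median of the described targets was 1.35. Of the 59 sarcomere genes on the array, 25 did not pass the detection filter and enter neither count, and 20 of these, DES, CKM, MYH7 and TNNI3 among them, were detected on 0 of the 6 arrays. Of the described targets, 10 did not pass it. The filter admits genes detected only with MEF2CA, and 7 of the measured described targets were undetected in the controls. With detection required on all arrays, the list adjusted p was weaker, at 0.012 for the described targets and 0.0042 for the sarcomere list. KLHL41, a stabiliser of muscle thin filaments, rose by 5.36 (SE 0.17, adjusted p = 2.4e-06). The lists share 7 measured genes, so they are not separate evidence. In the smooth muscle list 8 of 11 members rose and 0 fell, also adjusted over the list alone (median 0.57, list adjusted p = 2.4e-05). MYH11, the smooth muscle myosin heavy chain, rose at least 19.4-fold, MYLK, the kinase of myosin light chain, rose by 2.25 (SE 0.09), the filament protein SYNM by 1.74 (SE 0.14) and the actin gene ACTG2 by 0.64 (SE 0.11). These 3 lists also passed with an estimated correlation, but less strongly. The list adjusted p was then 0.013 for the described targets, 0.013 for the sarcomere list and 0.046 for the smooth muscle list.

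The transcription factors that start skeletal muscle and heart development were mostly not measurable. MYOD1, MYF5, MYF6, MYOG, GATA4, TBX5 and MYOCD did not pass the detection filter. Of the 4 measured myogenic regulators 2 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.25). ISL1, which acts in heart and motor neuron progenitors, rose by 2.27 (SE 0.23, detected on 1 of 3 control arrays), EYA1 rose by 1.59 (SE 0.13) on 1 probe and stood at 0.55 on another (adjusted p = 0.14, detected on 2 of 3 control arrays), and TBX1 fell by 0.67 (SE 0.17, adjusted p = 0.024). TBX1 did not pass without vector control replicate 2 (adjusted p = 0.078), without control replicate 3 (0.067) or without MEF2CA replicate 2 (0.056), and its other probes gave -0.78, -0.70 and -0.23 (detected on 2, 1 and 2 of 3 MEF2CA arrays).

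Class II histone deacetylases and other MEF2 regulators changed in both directions. In that list 5 of 10 measured members rose and 2 fell, also adjusted over the list alone (median 0.19, list adjusted p = 0.35). With median scaling 3 rose and 2 fell (median 0.04). HDAC9, a repressor of MEF2, rose at least 15.0-fold on a probe undetected in the controls. Its 3 other probes, of which 1 was detected on all control arrays, rose less. Their fitted values were 0.89, 2.08 and 3.79 (all past the test). HDAC5 rose by 1.45 (SE 0.21, detected on 1 of 3 control arrays) and HDAC4 by 1.30 (SE 0.15). MAPK7, a kinase of MEF2, fell by 0.61 (SE 0.09) on 1 probe and stood at -0.35 on another (adjusted p = 0.068).

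**Figure D2:**
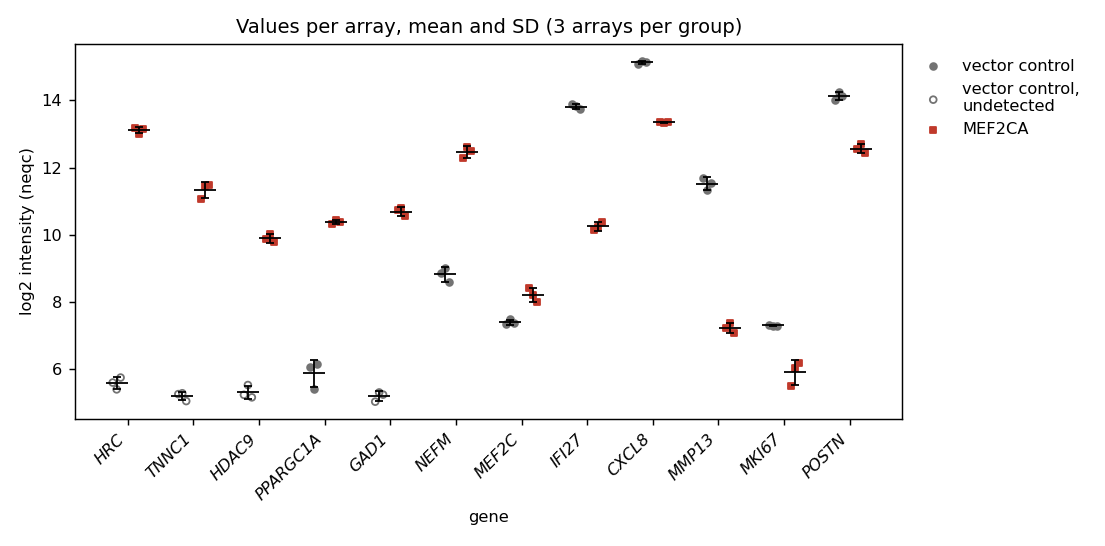
Log2 intensity (vertical axis) of 12 genes on each array, with vector control arrays as grey circles and MEF2CA arrays as red squares. Horizontal bars are means and whiskers SD over 3 arrays. Open symbols mark a group in which the probe was detected on 0 arrays, where the values are background signal. HRC reached 13.11 with MEF2CA from below detection, and IFI27 fell from 13.82 to 10.25.

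The genes that fell most include secreted factors, interferon-induced genes and chemokines. The collagenase MMP13 fell by 4.29 (SE 0.14, adjusted p = 2.7e-06), from 11.52 ± 0.19 to 7.23 ± 0.15 (SD, n = 3), or 19.5-fold. The death ligand TNFSF10 fell by 3.74 (SE 0.15) and was detected on 1 of 3 MEF2CA arrays. The chemokine CCL7 fell by 3.59 (SE 0.10) and CCL5 by 2.65 (SE 0.26). IFI27 fell by 3.57 (SE 0.10, 11.8-fold), the antiviral 2'-5' oligoadenylate synthetase OAS2 by 2.99 (SE 0.10) and the antiviral GTPase MX2 by 2.59 (SE 0.10). IDO1, an enzyme of tryptophan breakdown, was at least 3.99-fold lower on a probe undetected with MEF2CA, and fell by 2.46 on another (detected on 2 of 3 MEF2CA arrays). The egg coat gene ZP4 fell by 2.60, the tight junction gene CLDN1 by 2.51, the immune receptor SLAMF8 by 2.51 (detected on 1 of 3 MEF2CA arrays) and ALDH1A3, an enzyme of retinoic acid synthesis, by 2.46. The highest adjusted p among these 12 genes was 0.00048.

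Interferon-induced genes fell throughout the measured list. Of 27 members 27 fell, also adjusted over the list alone, with a median of -1.78 (list adjusted p = 2.6e-17). With cyclic loess 26 passed as lower. RSAD2, an antiviral enzyme, fell by 2.46 (SE 0.16, adjusted p = 6.1e-05). Inflammatory genes under NF-kB fell as well, 14 of 15 members over all probes tested and 15 adjusted over the list alone (median -1.04, list adjusted p = 1.1e-07). The chemokine genes CXCL2, CXCL8 and CXCL1 fell by 2.09 (SE 0.12), 1.78 (SE 0.09) and 1.62 (SE 0.22), and the adhesion molecule VCAM1 fell by 1.47 (SE 0.12). Both lists also passed with an estimated correlation, but less strongly (list adjusted p = 0.013 for interferon and 0.025 for NF-kB).

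Markers of leukocytes, which also express such genes, did not move together. Of 5 measured members of the microglia and leukocyte list 1 rose and 0 fell, also adjusted over the list alone (median -0.18, or -0.07 without background correction, mean 0.54, list adjusted p = 0.74). The chemokine receptor CX3CR1 rose at least 9.32-fold, and its other probe rose less, by a fitted 0.90 (adjusted p = 0.011). The pan-leukocyte gene PTPRC and the myeloid genes CSF1R, TYROBP and SPI1 were detected on 0 of the 6 arrays.

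Proliferation genes fell. In the cell cycle list 30 of 34 members fell and 1 rose, also adjusted over the list alone (median -0.89, list adjusted p = 6.4e-11). The list also passed with an estimated correlation, but less strongly (list adjusted p = 0.013). The phosphatase gene CDC25C fell by 1.56 (SE 0.12), the proliferation marker MKI67 by 1.39 (SE 0.18, detected on 2 of 3 MEF2CA arrays) and RRM2, a subunit of ribonucleotide reductase, by 1.34 (SE 0.15). NUSAP1, a spindle protein, was the member that rose, by 1.24 (SE 0.11), with 1.29 on its other probe.

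Targets of p53 and regulators of apoptosis did not shift as lists. Of 23 p53 targets 3 rose and 5 fell, or 4 and 5 adjusted over the list alone (median -0.14, list adjusted p = 0.82). The balance turned with the scaling, from 4 higher and 3 lower with cyclic loess (median -0.06) to 2 and 6 with median scaling (median -0.26). The cytokine gene GDF15 fell by 1.72 (SE 0.11) and the stress gene GADD45A rose by 1.00 (SE 0.11). BAX, which promotes apoptosis, rose by 0.73 (SE 0.11) on 1 probe and stood at 0.45 on another. Of 18 apoptosis regulators 4 rose and 5 fell, also adjusted over the list alone (median -0.28, list adjusted p = 0.48). Here cyclic loess gave 4 higher and 3 lower, median scaling 3 and 8, and no background correction 4 and 8. BCL2A1 fell by 1.19 (SE 0.22) and BIRC5, which also acts in mitosis, by 1.16 (SE 0.11). CASP8 was not detected with MEF2CA and was at least 1.30-fold lower.

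Genes of mesenchyme and extracellular matrix were detected throughout and mostly fell. Of 19 members 12 fell and 3 rose, or 13 and 4 adjusted over the list alone, with a median of -0.51 (list adjusted p = 0.037). The list did not pass with an estimated correlation (adjusted p = 0.46) or with the replicate number as a block (0.052). POSTN, a matrix protein, fell by 1.57 (SE 0.11), fibronectin FN1 by 1.06 (SE 0.13) and the collagen gene COL6A3 by 0.99 (SE 0.09). In the controls POSTN was at 14.13, FN1 at 11.12 and COL6A3 at 15.40 on the log2 scale. CCN1, a matricellular protein, rose by 1.67 (SE 0.12).

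Neuronal genes changed in opposite directions within each list. Of 19 genes of neuronal structure 6 rose and 8 fell, also adjusted over the list alone (median -0.14, or -0.27 with median scaling, mean 0.26, list adjusted p = 0.97). The neurofilament gene NEFM rose by 3.65 (SE 0.15, adjusted p = 7.2e-06), the adhesion molecule NCAM1 by 2.01 (SE 0.09), the motor protein KIF5C by 1.66 (SE 0.10) and MAP2 by 1.59 (SE 0.19), with 0.17 on 1 other MAP2 probe (adjusted p = 0.71, detected on 2 of 3 control arrays). Of 17 genes of synapse and excitability 7 rose and 3 fell, also adjusted over the list alone (median -0.02, or 0.06 with cyclic loess, mean 0.62, list adjusted p = 0.16). GAD1, the GABA-synthesising enzyme, rose at least 26.1-fold on its brightest probe, while its other probes gave -0.49 (detected on 2 control and 1 MEF2CA arrays) and 0.35 (1 and 2 arrays), neither past the test. The synaptotagmin gene SYT4 rose at least 5.60-fold, the glutamate receptor gene GRIA2 at least 2.71-fold and SYT1 by 1.64 (SE 0.17). The synapse list passed under 2 of 18 alternatives, with adjusted p from 0.033 to 0.33. Of 10 proneural and early neuronal transcription factors 3 rose and 3 fell, or 4 and 3 adjusted over the list alone, and 4 and 2 with cyclic loess (median 0.07, or 0.03 without background correction and 0.14 with cyclic loess, list adjusted p = 0.82). POU3F2, which acts in neuronal differentiation, fell by 1.91 (SE 0.12) and EBF1 rose by 0.61 (SE 0.09). DLX5 rose by 0.63 (SE 0.15, adjusted p = 0.021) but did not pass without control replicate 1 (0.066), control replicate 2 (0.065), MEF2CA replicate 1 (0.070) or MEF2CA replicate 3 (0.062). NEUROG1, NEUROD2 and TBR1 did not pass the detection filter.

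Among 14 measured neural progenitor genes 3 rose and 5 fell, or 4 and 5 adjusted over the list alone (median -0.25, list adjusted p = 0.74). Without background correction 5 rose and 6 fell, and with median scaling 2 and 7 (median -0.42). SOX3 fell 2.83-fold (adjusted p = 0.00020) and the glutamate transporter gene SLC1A3 by 0.93 (SE 0.11). FABP7, a fatty acid binding protein of radial glia, rose by 0.79 (SE 0.16), and DACH1 rose by 1.17 (SE 0.15) on 1 probe and stood at 0.28 on another (detected on 1 control and 2 MEF2CA arrays). SOX1, PAX6 and OTX2 were detected on 0 of the 6 arrays. Of 6 astrocyte and oligodendrocyte genes 1 rose and 2 fell, or 2 and 2 adjusted over the list alone or with cyclic loess (list adjusted p = 0.82). OLIG2, a factor of the oligodendrocyte lineage, rose at least 2.61-fold, PDGFRA fell by 1.11 (SE 0.12) and GJA1, the gap junction protein of astrocytes, fell by 0.65 (SE 0.13).

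Markers of other lineages gave mixed results. Of 8 pluripotency genes 1 rose and 3 fell, also adjusted over the list alone (median -0.14, or -0.26 with median scaling, mean 0.39, list adjusted p = 0.69). LEFTY2, an inhibitor of Nodal signalling, rose at least 39.6-fold, and LIN28B, a regulator of let-7 microRNAs, fell by 0.86 (SE 0.10). CD24 and DNMT3B stood at -0.53 and -0.39 and passed (adjusted p = 0.019 and 0.041), but neither passed in several fits without 1 array. Their other probes did not pass, at -0.35 for CD24 and -0.42 and -0.12 for DNMT3B (adjusted p = 0.31, 0.13 and 0.62). For CD24, leaving out control replicate 1 or 3 or MEF2CA replicate 1 or 3 gave 0.065, 0.061, 0.061 and 0.061. For DNMT3B, leaving out control replicate 1 or 2 gave 0.12 and 0.10, and leaving out MEF2CA replicate 1, 2 or 3 gave 0.068, 0.073 and 0.11. Of 11 neural crest genes 2 rose and 3 fell, or 2 and 5 adjusted over the list alone (median -0.12, or -0.28 with median scaling, list adjusted p = 0.74). ERBB3 rose at least 4.06-fold and NGFR by 0.87 (SE 0.18), and SOX9 fell by 1.04 (SE 0.13) and TFAP2A by 0.93 (SE 0.19). Of 4 endoderm and mesoderm genes 2 rose and 0 fell, also adjusted over the list alone (median 0.80, list adjusted p = 0.21). The median was 0.38 with the 2 members undetected in the controls at their bounds, and 0.34 without background correction. FOXA2 and FOXA1, factors of endoderm and floor plate, rose at least 4.07-fold and 1.74-fold from below detection. Of 8 endothelial genes 2 rose and 1 fell, or 3 and 1 adjusted over the list alone (list adjusted p = 0.65). The adhesion molecule PECAM1 fell by 1.36 (SE 0.17), the coreceptor ENG rose by 0.76 (SE 0.11) and the cadherin CDH5 rose at least 1.07-fold.

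Immediate early genes changed in both directions. Of 26 members 8 rose and 8 fell, or 8 and 9 adjusted over the list alone, and 8 and 6 with cyclic loess (median -0.19, or -0.11 with cyclic loess, list adjusted p = 0.98). ATF3 rose 2.38-fold (adjusted p = 0.00069) and NPAS4, an activity-regulated factor, by 1.18 (SE 0.21, detected on 2 of 3 control arrays), while EGR1 fell by 1.24 (SE 0.12). In the list of the unfolded protein and ATF4 response 3 of 20 members rose and 11 fell, or 3 and 12 adjusted over the list alone (median -0.45). The list did not pass (adjusted p = 0.051), and it passed under 8 of 18 alternatives (adjusted p from 0.0071 to 0.10). DDIT4 fell by 1.13 (SE 0.11), CEBPB by 0.83 (SE 0.10), and PPP1R15A rose by 0.81 (SE 0.09). Of 13 heat shock genes 3 rose and 2 fell, or 4 and 2 adjusted over the list alone, but 2 and 4 with median scaling (median -0.09, or -0.29 with median scaling, mean 0.23, list adjusted p = 0.82). The small heat shock gene CRYAB rose at least 8.32-fold and HSPB1 by 0.77 (SE 0.10).

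Metabolic lists moved little as groups. Of 30 genes of oxidative phosphorylation 3 rose and 2 fell, or 3 and 1 adjusted over the list alone, but 2 and 3 with median scaling (median -0.02, or -0.22 with median scaling, mean 0.13, list adjusted p = 0.82). PPARGC1A, a coactivator of mitochondrial biogenesis, rose by 4.49 (SE 0.20, adjusted p = 1.0e-05, detected on 2 of 3 control arrays), and TFAM, which maintains mitochondrial DNA, fell by 0.52 (SE 0.11). SDHC rose by 0.66 (SE 0.12) on 1 probe and stood at 0.14 on another. Of 22 genes of hypoxia and glycolysis 1 rose and 8 fell, also adjusted over the list alone (median -0.22, or -0.36 with median scaling, list adjusted p = 0.083), and the list passed under 3 of 18 alternatives (adjusted p from 0.022 to 0.15). VEGFA fell by 0.84 (SE 0.12) and PFKFB3 by 0.72 (SE 0.10), with -0.45 on the other PFKFB3 probe (adjusted p = 0.078), while ERO1A rose by 1.11 (SE 0.09). Of 17 genes of cholesterol synthesis 0 rose and 1 fell, INSIG1 by 0.52 (SE 0.11), also adjusted over the list alone (list adjusted p = 0.99), but 3 rose and 2 fell without background correction and 0 and 4 with median scaling.

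Signalling lists also held members in both directions. Over the 5 other normalizations, the balance of higher and lower members turned in 9 of the 32 lists, 0 of them past the list test. The median moved by over 1.5 times in 20 lists, of which 1, the sarcomere list, passed the list test. Of 17 Notch pathway genes 3 rose and 5 fell, or 4 and 6 adjusted over the list alone (median -0.30, mean 0.12, list adjusted p = 0.88). Cyclic loess gave 4 higher and 3 lower and median scaling 2 and 7, and the median was -0.16 without background correction. The ligand gene JAG2 rose by 4.25 (SE 0.20, detected on 1 of 3 control arrays), HEY2 rose at least 2.87-fold and HEY1 fell by 1.16 (SE 0.11). Of 13 Wnt pathway genes 3 rose and 7 fell, also adjusted over the list alone (median -0.82, list adjusted p = 0.12). SFRP2 fell by 2.30 (SE 0.13), DKK1 by 1.44 (SE 0.10) and NKD2 by 1.30 (SE 0.12). These encode inhibitors of Wnt signalling, and RSPO3, which enhances it, was at least 2.65-fold lower. Of 19 genes of BMP and TGF-beta signalling 2 rose and 4 fell, or 2 and 5 adjusted over the list alone (median -0.22, list adjusted p = 0.25). The BMP antagonist GREM1 fell by 1.90 (SE 0.11), ID1 by 1.75 (SE 0.10) and ID2 by 1.03 (SE 0.10), while ID3 rose by 0.80 (SE 0.09). Of 28 axon guidance genes 6 rose and 13 fell, also adjusted over the list alone (median -0.34, list adjusted p = 0.48). EPHA5 rose at least 2.77-fold and PLXNA2 by 1.76 (SE 0.11) on 1 of 2 probes, while PLXNA4 fell by 1.81 (SE 0.32, detected on 1 of 3 MEF2CA arrays) and SEMA3C by 1.64 (SE 0.13).

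**Figure D3:**
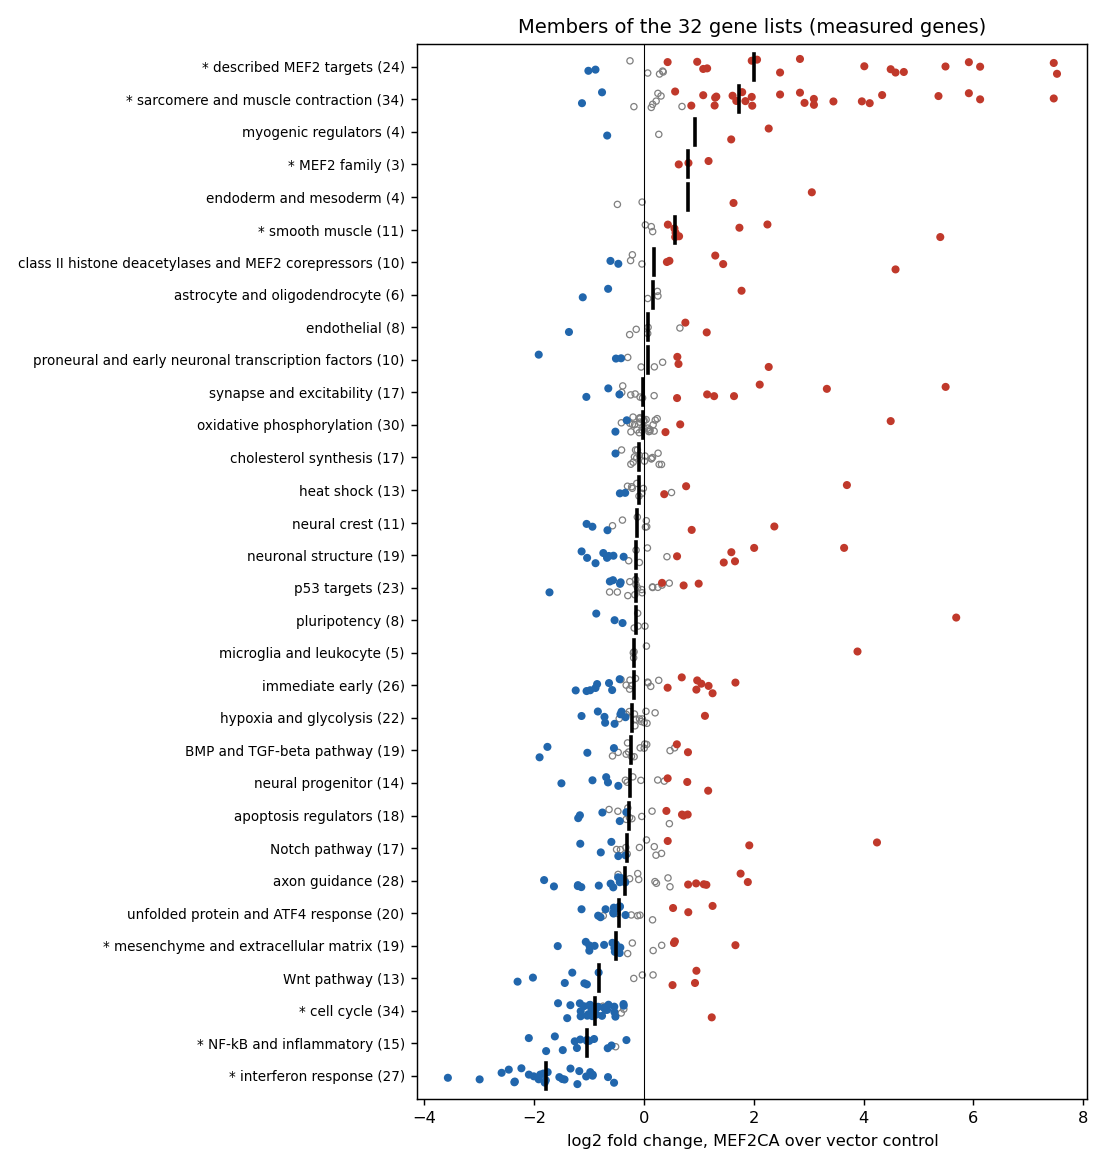
Log2 fold change of MEF2CA over vector control (horizontal axis) for each measured member of the 32 gene lists, ordered by list median (black bar), with the number of measured members in brackets. Filled points passed the test over all probes (red higher, blue lower) and open points did not. Stars mark the 8 lists past the list test, from a median of 2.01 for described MEF2 targets to -1.78 for the interferon response.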

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

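The counts of higher and lower probes and of shifted gene lists stayed within 1.5 times of 3044, 3241 and 8 under every alternative run except fry for the lists, and no gene list past the test changed direction. The number of probes changed at least 2-fold (1912) was 907 without background correction, 1170 with normexp and an offset of 50, 906 from the deposited normalized values, 1167 with detection required on all arrays (17646 probes tested) and 1270 of 12680 genes with the probes of a gene averaged. A larger offset or uncorrected background shrinks folds of dim probes by construction, and the last 2 settings test fewer items. For gene lists, fry's directional test, which does not compare a list with other genes, passed 23 of 32 lists. Median scaling moved the median log2 fold change of all probes to -0.14, from -0.057. Leaving out 1 array gave 2441 to 2614 higher probes, 2352 to 2631 lower probes, 1903 to 1935 changed at least 2-fold and 7 to 9 lists. With the replicate number as a block, 2561 probes were higher, 2621 lower and 1905 changed at least 2-fold, and 7 lists passed. The mesenchyme list then had an adjusted p of 0.052 (0.0047 to 0.052 over all alternatives). Same-numbered arrays deviated with correlations of 0.019, 0.010 and -0.011, and not every array correlated best with its own number, so the numbers were not taken to pair samples. Of 2296 values of 130 named probes under alternatives, 2245 kept their direction and call, 51 lost the call and 0 reversed. The losses fell on 10 probes, those of TBX1, DLX5, CD24, DNMT3B, POLH, BCL2, HSPD1, BAG3, NDUFV2 and MFNG; their cause was not tested. Slide as a block was not run, since slides are not identified. Signal close to background limits the folds of dim probes, which are compressed there.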

Other observations

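The gene family tests and the leukocyte, untransfected-culture, mesenchymal-cell and other-probe tests were chosen only after the results were seen, and the interferon list was picked for its medians under other normalizations after its shift was seen, with the bounds set before those medians were.

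Some gene families not singled out above held more higher or more lower genes than the background of all genes. Genes were grouped by the letters that begin their symbols, and 413 groups with at least 5 measured genes were tested in both directions (826 one-sided Fisher's exact tests, Benjamini-Hochberg adjusted). This test treats the genes of a group as independent, so its p-values may be too small where members move together. Of all 12680 genes, 2005 were higher and 2153 lower by their brightest probe. All 5 measured HSPB genes, which encode small heat shock proteins, rose (adjusted p = 0.022). HSPB3 rose by 4.04 (SE 0.18, detected on 1 of 3 control arrays) and HSPB6 by 3.50 (SE 0.12, detected on 2 of 3 control arrays). Of 27 KLHL genes 12 rose and 4 fell (adjusted p = 0.046, median 0.25, or 0.10 with median scaling), so they moved in both directions, with KLHL40 at least 3.82-fold and KLHL30 at least 4.40-fold higher. Of 11 measured SCARNA genes, small RNAs that guide modification of spliceosomal RNA, 7 rose (adjusted p = 0.046), and 0 fell except under 3 of the 5 other normalizations, where 1 fell. SCARNA14 rose at least 2.93-fold. It is 1 of 5 SCARNA genes that were undetected in the controls. All 5 rose and passed the detection filter only through the MEF2CA arrays, so the filter favoured this count.

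Chemokine genes of the CXCL group fell in 10 of 12 cases (adjusted p = 0.00076), with CXCL10 down by 2.36 (SE 0.09) and CXCL6 by 2.25 (SE 0.10), while CXCL13, a B cell attractant, rose at least 11.8-fold. Of 9 genes beginning with IRF, 8 fell (adjusted p = 0.0022). Among them, IRF1 fell by 1.33 (SE 0.11) and IRF8 by 1.07 (SE 0.10), and 3 others encode IRF2-binding proteins. The IFI group fell in 7 of 9 cases (adjusted p = 0.022), and the IFI and IRF groups had 6 and 7 lower genes with cyclic loess. Replication genes of the MCM group fell in 7 of 10 cases (adjusted p = 0.041) and cell division genes of the CDCA group in 6 of 7 (adjusted p = 0.024). These groups are not separate from the gene lists. The interferon list holds 4 IFI genes, 3 IRF genes and CXCL10, the inflammatory list 3 CXCL genes, the cell cycle list 6 MCM genes, and the sarcomere list HSPB7 and KLHL41. HSPB7 is also among the described MEF2 targets, and HSPB1 is in the heat shock list. The medians of all 8 groups kept their sign under the 5 other normalizations, but some moved by over 1.5 times. Without background correction the median was -1.23 for CXCL, against -1.94 (-1.70 with undetected genes at their bounds), 2.07 for HSPB, against 3.50, and 0.55 for SCARNA, against 1.37 (1.19 at the bounds).

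Probes of a single gene sometimes parted. GAD1 stood at -0.49 on 1 probe (detected on 2 control and 1 MEF2CA arrays) and was at least 26.1-fold higher on another, and RTN4 rose by 0.44 on 1 probe and at least 52.4-fold on another (these higher probes were undetected in the controls). SPC25, a kinetochore gene, rose by 0.93 on 1 probe and was at least 1.55-fold lower on another (both past the test). EGFR rose by 0.98 on 1 probe and fell by 0.47 on another, and ADK, adenosine kinase, rose by 1.94 on 1 probe (detected on 1 of 3 control arrays) and fell by 0.36 on another. The probes' places in the transcripts were not used here, so transcript variants were not separated from other sources.

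The interferon list fell in all 27 members, or in 26 with cyclic loess. Scaling or background correction as the whole source is argued against by the list's median, which was -1.46 at its nearest to 0 and -1.94 at its lowest over 5 other normalizations. The pan-leukocyte gene PTPRC and the myeloid genes CSF1R, TYROBP and SPI1 were detected on 0 of the 6 arrays. These genes thus showed no leukocytes in the controls that could be lost. A loss of leukocytes too few for these probes to detect stays open. The 5 measured leukocyte genes had a median of -0.18 and 0 fell, but this neither met nor failed the bounds set. CD68, at 10.39 in the controls, stood at 0.05 (95% interval -0.24 to 0.34) and HLA-DRA, at 8.81, at -0.19 (-0.46 to 0.08), which goes against a loss that would lower these transcripts as far as the interferon list. Other cells also express both genes, and such a baseline can hide a small share of leukocytes. A bound on single members was tried after that outcome and set aside, because CD14 and AIF1 lie near the detection limit in the controls (6.27 and 6.92, CD14 detected on 2 of 3 MEF2CA arrays) and CX3CR1 is undetected there, so they had little or no room to fall. A response to transfection that differed between the cultures cannot be told apart from an effect of MEF2CA, since 0 arrays are of untransfected cells.

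Many genes were detected only with MEF2CA. Probes detected on all 3 MEF2CA arrays and 0 control arrays numbered 573, against 142 the other way. A lower detection threshold on the MEF2CA arrays is argued against by the probes at least 4-fold apart, 212 against 9 by fitted values, a ratio of 23.6, and 150 against 1 by their bounds. Cross-hybridisation of single probes stays open as the source for part of these genes. Of the 168 genes at least 4-fold apart by fitted values, 73 have another probe on the array, with 130 such probes. Of these probes, 55 (42.3%, exact 95% interval 33.7 to 51.3%) were higher in a fit of all probes, against 7.07% of all named probes. Genes without another probe are not covered. Cross-hybridisation as the general source was set to give a share no higher than that background. The interval lies above it, which argues against this general source for the 73 genes covered, taken as a set. The interval also includes the bound of 50% set for deciding against this source, so by that bound the test did not decide. Probes below detection can seldom pass the test, which made the bound hard to reach. Of the 60 other probes that did not pass the detection filter, 3 were higher. An effect of MEF2CA on genes silent in these cells stays open as well, and was not tested.

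The mesenchyme and extracellular matrix list fell in 12 and rose in 3 of its members. The test for a lower share of mesenchymal cells as the whole source assumed that it would lower all members alike. The 95% interval of 57.9% of them left out the list median of -0.51. Members that other cells also express would fall less, so uneven falls cannot decide on this source. A lower share of such cells, in whole or in part, and a change in matrix genes within the neural stem cells stay open.

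With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. For probes changed, 1 of the 10 splits gave as many as the real one, the real split itself, with 6285 against a highest other of 0. For probes changed at least 2-fold it was 1 of 10, with 1912 against 0. For gene lists it was 1 of 10, with 8 against 6. Every other split puts arrays of both groups on each side. Part of the MEF2CA difference then stays between the sides, and the rest adds to the spread within them. The highest other counts are therefore not levels expected without any difference. Of the 22086 probes, 8742 had an unadjusted p under 0.05 in limma's fit of the real split.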
